A study of Drosophila melanogaster with 21 samples.

How the data were processed

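Transcript levels of Drosophila melanogaster oocytes and eggs were measured on 21 two-colour cDNA arrays. Per the labels, the Cy3 channel of each array held the sample and the Cy5 channel held RNA of wild-type (w1118) stage 14 oocytes, the mature oocytes of the ovary. The samples were stage 14 oocytes of smg females and unfertilized eggs of smg and wild-type females collected at 0-2 h, 2-4 h and 4-6 h, which made 7 groups of 3 arrays. The wild-type stage 14 oocytes served as the common reference and had no sample arrays of their own. Dyes were never exchanged. A comparison of 1 group with the reference therefore holds any gene-specific dye bias and leaves out the spread of the reference, whereas a comparison between groups of arrays cancels that bias. The replicate numbers carried by the groups followed the order of the records and paired no arrays.

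Per the labels, the authors primed the labelled cDNA at random sites so that the length of the poly(A) tail did not affect labelling, checked RNA on northern blots with stable rpA1 and unstable Hsp83, scanned the slides at 16 bits, quantified the spots with an adaptive method and normalized to rpA1 and rp49. Per the file headers, the deposited scanner files hold the spot intensity and the local background intensity of both channels in arbitrary scanner units. The deposited value tables hold log2 ratios of sample over reference. Checked against the scanner files, these log2 ratios were the ratio of the spot intensities without background subtraction. They carried no shift on the 12 smg arrays and 1 constant shift per array, from -0.925 to 0.545, on the 9 wild-type arrays. The value tables were used only as an alternative.

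Each array held 27648 spots in 48 grids of 24 by 24. Control, empty and failed spots numbered 4160, and the 23488 gene spots made 11744 probes printed as pairs of spots, with 10485 names. Array names were CG numbers or clone names. Of these names, 8734 matched a locus tag of the Release 6 gene table, 454 a synonym, 86 a clone listed among synonyms and 133 several genes. A further 40 CG numbers were absent from the table and 1038 clones had no gene name. Names that led to the same gene were merged into 10390 genes, called by current symbols. The assembly gave names and gene order only. Probes of cDNA do not separate closely related genes, such as members of the actin, yolk protein or Gapdh families.

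Analysis ran in R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8), and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Background was corrected with normexp and an offset of 50, and log2 ratios were normalized by loess within each array, with control and empty spots at weight 0. Between 122 and 769 spots per array were left out because of the quality marks in the files, and 0 to 3 spots per array were saturated. Both spots of a probe were averaged and the probe with the brightest reference represented its gene. Genes were tested when the mean raw Cy5 reference intensity over all arrays was at least 3000, the level that the labels give for maternal expression. This left 5808 genes with values, from 5871 at or above the level. Loess sets the bulk of transcripts on each array near 0, so every change is relative to the other transcripts of the egg and not to the egg.

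All 21 arrays entered 1 limma fit with a mean for each group, 14 residual degrees of freedom, a prior of 6.2 degrees of freedom and a prior SD of 0.27. Adjusted p is the Benjamini-Hochberg value over the tested genes. A gene was called lower or higher when adjusted p was below 0.05 and the change was at least 1.5-fold. Changes are log2 values given with ± SE from the fit, n = 3 arrays per group. The p-values measure the spread between arrays of a group, and the labels do not say whether these arrays held separate collections of eggs or repeated hybridizations. Where no array of a group rose above the 95th percentile of empty spots, the change is given as at least a number of folds. It was computed with that group raised to the 95th percentile of the empty spots after background correction, and no size is given where both sides were undetected. Such a value still holds any dye bias.

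A further shift of each array to set rpA1 and rp49 to 0 was to be used unless its pooled SD within groups was above 0.2. The SD was 0.27, so the shift was kept as an alternative. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The lists were known unstable maternal transcripts, stable normalizers, cytoplasmic ribosomal proteins, translation factors, proteasome, CCT chaperonin with the HSP70 and HSP90 system, small heat shock proteins, glycolysis, nuclear-encoded oxidative phosphorylation, cell cycle, DNA replication, germ plasm and germline, mRNA decay and translational repression, meiosis and egg activation, core histones and variants, tubulins and actins, and early zygotic genes, with markers of follicle cells and eggshell, yolk and fat body, and muscle for other cell types. A gene could be in several lists. One member of the list of known unstable transcripts was not analysed here.

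Genes named in 4 main comparisons were the 6 largest decreases and 6 largest increases among called genes with a symbol other than a CG number and with arrays of both sides separated, up to 3 called members of each list with the largest changes or else its brightest member, and 7 genes named in each comparison (smg, Hsp83, osk, bcd, stg, CycB and RpL32). The groups, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. Genes named in the other comparisons were chosen after their values were seen.

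Alternatives were no or plain background subtraction, median centring or print-tip loess in place of loess, shifts to rpA1 and rp49 or to ribosomal protein genes, the value tables, the mean of all probes, other or no reference levels, no minimum fold, limma with a trend and robust prior, array quality weights, only the arrays compared, slide series as a random or fixed block, other definitions of the class of transcripts lower in wild type, and leaving out each array in turn. The other scalings counted below were median centring, both shifts and the value tables. The value tables differ in more than scaling, since they hold no background subtraction and no loess. Slide series A to D came from the slide numbers in the labels and scan days from the scanner files. Blocks of scan day and comparisons within 1 slide series or 1 scan day were added after seeing the data. The arrays of a group within 1 series were few, and a lone array was assumed to vary like the others.

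The procedure was tested on simulated data drawn with the fitted spread of each gene. For wild-type 4-6 h eggs against the reference, 43.6% of genes with a 1.5-fold change, 93.0% with a 2-fold change and 0.0927% of unchanged genes were called. For smg 4-6 h eggs against smg stage 14 oocytes, the shares were 17.8%, 70.2% and 0.123%. When the background-corrected Cy3 signal of 200 genes was changed by 1 on the log2 scale on the wild-type 4-6 h arrays, 99.5% of them were called in the right direction, with median sizes of 1.16 for increases and 1.19 for decreases.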

Results

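The series compared maternal transcripts of Drosophila oocytes and unfertilized eggs of wild-type females and of smg females, named after the gene of the RNA-binding repressor Smaug. Unfertilized eggs are activated but do not start zygotic transcription, so the fall of maternal transcripts can be followed in them without an embryo. The 21 arrays made 7 groups of 3, namely smg stage 14 oocytes and smg and wild-type eggs at 0-2 h, 2-4 h and 4-6 h. Each was hybridized against wild-type stage 14 oocytes. Median raw spot intensities ran from 972 to 5632 in Cy3 and from 1104 to 6720 in Cy5. On the arrays, 22.9% to 75.8% of gene spots in Cy3 were above the 95th percentile of empty spots. Log2 ratios of arrays of the same group correlated across genes, which are not independent replicates, with a mean r from 0.42 in smg stage 14 oocytes to 0.78 in wild-type 4-6 h eggs. The number of arrays per group limits the precision.

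The smg transcript (CG5263), a product of the gene altered in the mutant females, had log2 ratios to the wild-type reference of -0.43, -0.59 and -0.38 in the 3 smg stage 14 arrays. It lay between -0.20 and 0.41 in the wild-type egg arrays. Relative to wild type of the same stage it was -0.47 ± 0.17 in stage 14 oocytes (adjusted p = 0.19), -0.50 ± 0.24 at 0-2 h (adjusted p = 0.35), -1.15 ± 0.24 at 2-4 h (adjusted p = 0.0015) and -0.89 ± 0.24 at 4-6 h (adjusted p = 0.0066). The call at 4-6 h was lost without smg 4-6 h replicate 2, which left -0.61, and with 3 of 4 other scalings. The value was -0.30 within slide series D. The allele was not given in the labels, and a cDNA probe would also detect a mutant transcript.

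The comparison of stage 14 oocytes asked whether maternal transcripts of smg females differed before egg activation. The transcripts of the yolk proteins, which fat body and follicle cells make, were higher in smg oocytes, by 1.84 ± 0.30 for Yp3, 1.60 ± 0.21 for Yp1 and 1.43 ± 0.31 for Yp2 (adjusted p = 0.002, 0.00011 and 0.014). Higher too were Arc1, related to retroviral Gag proteins, at 1.48 ± 0.16 and Usp14, a ubiquitin protease of the proteasome, at 1.46 ± 0.16. The polarity gene sdt, of the Crumbs complex, was 1.43 ± 0.26, although another sdt probe gave -0.20. Lower were Zyx, an actin-associated protein of cell junctions, at -1.09 ± 0.19 and Srp68, of the signal recognition particle, at -1.05 ± 0.18. So were SmE, a core protein of spliceosomal snRNPs, at -1.05 ± 0.14, and the tetraspanin Tsp66E at -1.04 ± 0.12. Sas-6, of the centriole, at -1.09 ± 0.27 and GstE6, a glutathione transferase, at -1.07 ± 0.27 were close to the threshold (adjusted p = 0.037 and 0.041). Srp68 and Tsp66E lie beside smg on chromosome arm 3L.

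In all, 41 transcripts were lower and 57 higher, of which 10 and 19 changed at least 2-fold. Of the 6 yolk and fat body genes tested, 3 were higher and 0 lower, the same when adjusted over the list alone (list test adjusted p = 2.3e-05, and 0.016 with an estimated correlation). DNA replication genes had a median of -0.22, with 21 of 24 negative and 0 called, 1 lower when adjusted over the list alone (adjusted p = 0.00015, and 0.024 with an estimated correlation). With the other scalings this median stayed below 0, from -0.068 to -0.24. RnrS, the small subunit of ribonucleotide reductase, was -0.68 ± 0.21 (adjusted p = 0.11). Among 41 cell cycle genes fzr, an activator of the anaphase-promoting complex, fell by 0.62 ± 0.13. Adjusted over the list alone, 2 were lower and 1 higher (adjusted p = 0.0015, and 0.061 with an estimated correlation, with a median near 0, -0.0062, after the shift to rpA1 and rp49). The muscle gene up, a troponin, was 0.80 ± 0.21 (adjusted p = 0.05), a call lost in 27 alternatives and not shared by its other probe (-0.14). The gene slbo, of the follicle cell list in which 0 of 2 genes were called, was 0.24 ± 0.13. The medians of the ribosomal protein and proteasome lists were -0.16 and -0.15 with 0 members called. Their list tests (adjusted p = 0.0014 and 0.0085) gave adjusted p = 0.68 and 0.42 with an estimated correlation. After the shift to rpA1 and rp49 both medians were near 0 (-0.0029 and 0.0045). Adjusted over the list alone, 1 meiosis gene was higher. Hsp83 (0.17 ± 0.21), osk (0.45 ± 0.18), bcd (0.046 ± 0.10), stg (-0.32 ± 0.13) and CycB (-0.31 ± 0.14) were not called, nor was RpL32, which was not above empty spots on the smg stage 14 arrays.

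Leaving out smg stage 14 replicate 1 left 35 calls in stage 14 oocytes and leaving out replicate 3 left 40. Among named genes, calls were lost for Sas-6 without replicate 1 (-1.08) or 3 (-0.62), for GstE6 in 19 alternatives (-0.65 without replicate 1, -1.22 without replicate 2 and -1.35 without replicate 3). They were also lost for Zyx without replicate 2 (-0.96), for Srp68 (-0.83) and sdt (1.06) without replicate 3, for fzr without replicate 1 (-0.63) or 2 (-0.52), and for Yp2 without any 1 of the 3 (1.22 to 1.54). The split of calls was 4 lower and 49 higher after the shift to rpA1 and rp49, which moved the median of all genes by 0.15. It was 14 and 65 after the shift to ribosomal protein genes, which moved it by 0.12, and 3 and 22 in the value tables.

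**Figure D1:**
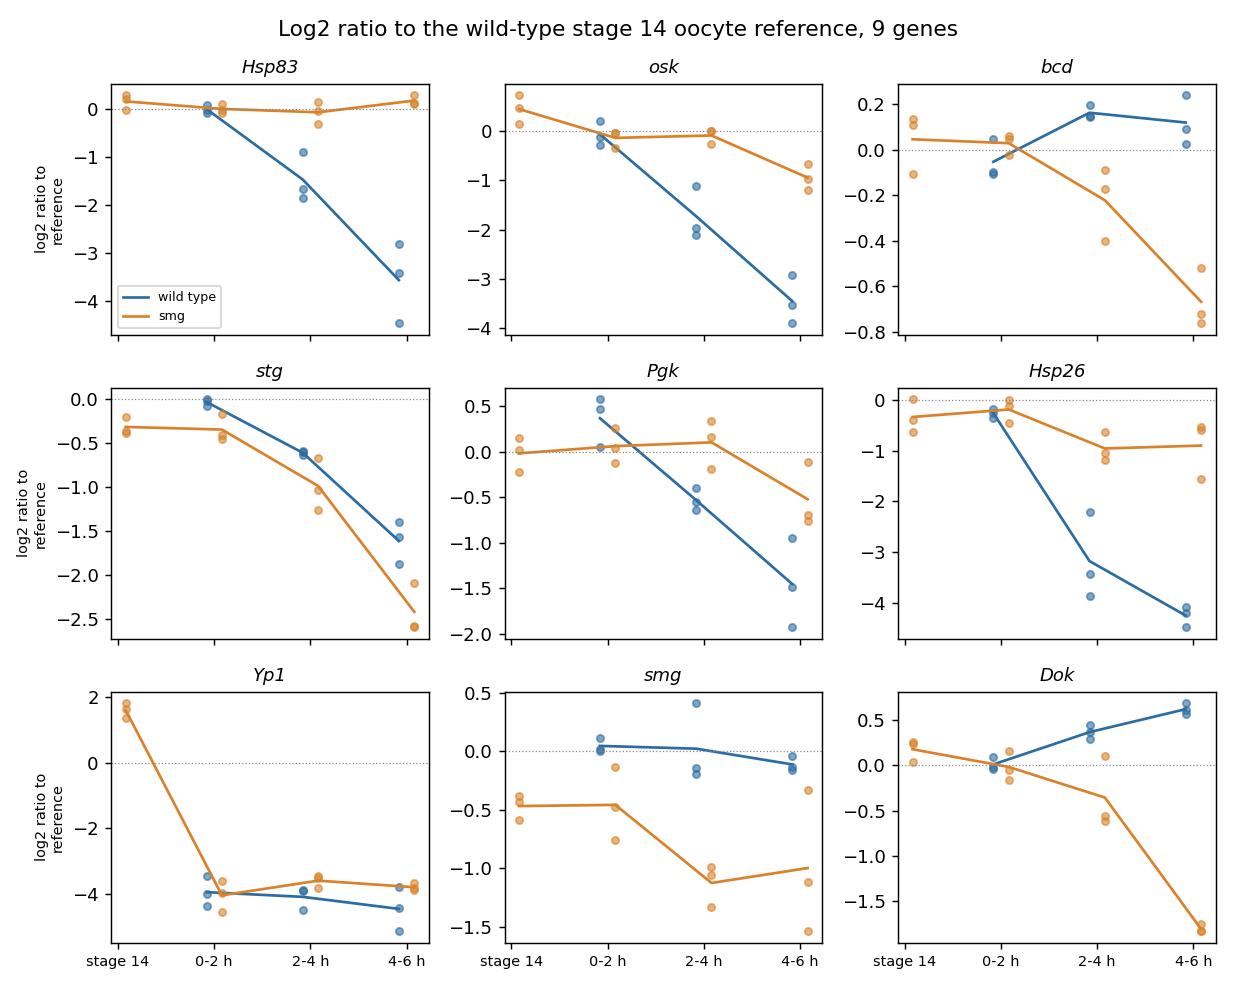
Log2 ratio to wild-type stage 14 oocytes (vertical axis) of 9 genes in each group of arrays by stage (horizontal axis), 1 point per array, with lines through the means of smg and wild type. Wild type has no stage 14 array. Hsp83 lay between -4.46 and -2.80 in the wild-type 4-6 h arrays and between 0.12 and 0.30 in the smg 4-6 h arrays, whereas stg was lower at 4-6 h in both.

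The wild-type time course asked which maternal transcripts fell after egg activation. By 4-6 h Hsp83, which encodes the HSP90 chaperone and served as the unstable transcript of the study's northern blots, had fallen by 3.56 ± 0.21 (adjusted p = 9.9e-12), and stg, the Cdc25 phosphatase, by 1.62 ± 0.13 (adjusted p = 1.2e-09). The largest falls by fitted change were in drpr, an engulfment receptor (-4.72 ± 0.19), the RNA-binding protein gene vig2 (-4.49 ± 0.19) and Yp1 (at least 15.1-fold). Also far down were del, of the piRNA cluster complex (at least 13.2-fold), Hsp26 (-4.26 ± 0.23) and Jabba, which anchors histones to lipid droplets (at least 15.5-fold). Transcripts that gained in relative level were EMC1, of the ER membrane complex (1.54 ± 0.31), the arrestin krz (1.35 ± 0.26) and the immune peptide BomT3 (1.29 ± 0.17). So did the deacetylase HDAC1 (1.24 ± 0.17), the splicing and transcription cofactor Bx42 (1.23 ± 0.13) and SmydA-8, a SET and MYND domain protein (1.22 ± 0.22). The calls of EMC1 and Bx42 were lost in the value tables. The transcript of bcd, the anterior determinant, was 0.12 ± 0.10 (adjusted p = 0.35), CycB was -0.14 ± 0.14 and smg -0.11 ± 0.17.

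Calls numbered 126 lower and 163 higher at 0-2 h, 1101 and 92 at 2-4 h, and 1527 and 495 at 4-6 h, where the lower ones made 26.3% of the tested genes. Of the 1527, 922 fell at least 2-fold, 942 had been lower at 2-4 h and 62 at 0-2 h. Their median change was -0.094 at 0-2 h, -0.78 at 2-4 h and -1.15 at 4-6 h. At 4-6 h 354 of them were not above empty spots, of which 163 fell at least 1.5-fold down to that level, and with such transcripts at that level the median was -1.06. At 0-2 h the lowest named values were those of Yp1 (at least 11.9-fold lower) and Jon99Fii, a digestive serine protease (-2.85 ± 0.68). At that age 3 of 6 yolk and fat body genes were lower and 1 higher (list test adjusted p = 0.0019, and 0.12 with an estimated correlation). Of 74 ribosomal protein genes 5 were lower at 0-2 h, 7 when adjusted over the list alone (adjusted p = 1.1e-06, and 0.65 with an estimated correlation).

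Of 11 glycolysis genes 10 were lower in wild-type 4-6 h eggs, among them PyK, pyruvate kinase (at least 7.40-fold), Gapdh1 (-3.64 ± 0.17) and Gapdh2 (-3.40 ± 0.26). Of 13 genes of the CCT chaperonin and HSP70/HSP90 system 9 fell, among them CCT7 (-3.47 ± 0.16) and CCT3 (-2.51 ± 0.15). All 3 small heat shock genes fell, Hsp26, Hsp27 (-4.19 ± 0.19) and Hsp23 (-0.63 ± 0.17). The call of Hsp23 was lost without wild-type 4-6 h replicate 1 (-0.54) or 3 (-0.47), after median centring (-0.48) and in the value tables (-0.48). Of 24 DNA replication genes 16 fell and 1 rose, with RnrS at -4.05 ± 0.21, RPA1, which binds single-stranded DNA, at -4.02 ± 0.13 and Gnf1, the large subunit of the clamp loader, at -2.90 ± 0.13. Of 22 germ plasm and germline genes 15 fell and 0 rose, with osk, which nucleates germ plasm, at least 9.59-fold lower, krimp, of the piRNA pathway, at -3.12 ± 0.11 and exu, needed to localize bcd, at -2.98 ± 0.19. List tests gave adjusted p = 4.1e-05 for glycolysis, 8e-05 for the chaperones, 0.0074 for small heat shock genes, 0.00066 for DNA replication, 8e-05 for germ plasm and 0.013 for the 2 known unstable transcripts. Each gave adjusted p = 0.098 with an estimated correlation.

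Of 41 cell cycle genes 15 fell and 2 rose, with endos, the PP2A inhibitor, at -3.42 ± 0.13, Cdk2 at -3.13 ± 0.12 and gnu, of the PNG kinase complex, at -2.97 ± 0.21 (adjusted p = 0.015, and 0.12 with an estimated correlation). Of 26 genes of mRNA decay and translational repression 12 fell and 0 rose, with the deadenylase subunits Pop2 at -1.89 ± 0.12 and twin at -1.64 ± 0.14 (adjusted p = 0.015, and 0.19 with an estimated correlation). Of 34 proteasome genes 15 fell and 4 rose, with Rpn7 at -3.10 ± 0.15, Rpn1 at least 7.35-fold lower and Rpn3 at -2.76 ± 0.19, whose other probe gave 0.57 (adjusted p = 0.14). Of 15 meiosis genes 6 fell and 1 rose, with the Polo inhibitor mtrm at -2.55 ± 0.21 and the kinesin nod at least 3.01-fold lower (adjusted p = 0.5). Of 18 oxidative phosphorylation genes 4 fell and 0 rose, with ATPsynbeta at -3.36 ± 0.17, ATPsynD at -1.26 ± 0.18 and SdhA at -1.14 ± 0.15 (adjusted p = 0.89). Of 17 translation factors 2 fell, eIF4E1 (-2.27 ± 0.17) and eIF2beta (at least 1.24-fold), and eIF3c rose by 0.71 ± 0.16 (0.48 and not called without wild-type 4-6 h replicate 1).

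Ribosomal protein genes had a median of 0.36, with 15 of 74 higher, such as RpL34a (0.95 ± 0.18) and RpL34b (0.82 ± 0.21; 0.36 and not called without wild-type 4-6 h replicate 3), and 1 lower, RpL23 (at least 2.00-fold). The list test gave adjusted p = 7.1e-07, and 0.23 with an estimated correlation. The counts were 3 lower and 1 higher with arrays shifted to these genes, and 1 and 0 in the value tables. RpL32 (rp49) rose by 0.76 ± 0.15 on its brightest gene probe, a call lost with both of these scalings (0.46 and 0.29). Its other gene probe, under the reference level, gave 1.12. The mean of all 20 rp49 spots, control spots included, showed no such rise, with -0.0837, 0.251 and -0.0825 on the wild-type 4-6 h arrays. Of 13 tubulins and actins 6 rose and 1 fell, with betaTub56D at 1.06 ± 0.20, betaTub85D at 0.91 ± 0.13 and Act87E at 0.91 ± 0.14 (adjusted p = 0.0016, and 0.14 with an estimated correlation). Both of these scalings gave 3 higher and 2 lower. Of 4 histone genes BigH1, the embryonic linker histone, fell by 1.23 ± 0.14 and His3.3A was 0.67 ± 0.13, with another probe at -0.049 and 0.47 without wild-type 4-6 h replicate 3. Yolk transcripts Yp2 (at least 3.44-fold) and Yp3 (-2.44 ± 0.30) fell with Yp1, 3 of the 6 in that list (adjusted p = 0.12). In limma 0 of 2 follicle cell genes were called (slbo -0.33 ± 0.13) and 1 of 7 muscle genes, up, was higher (0.70 ± 0.21). That call was lost without wild-type 4-6 h replicate 3 (0.38) or 1 (0.64) and as the mean of its probes (0.17). In limma 0 of 11 early zygotic genes were called at 4-6 h, and odd was -0.071 ± 0.11. With no filter on the reference, 0 of 27 were lower and 1 higher. Counts adjusted over the list alone were the same as over all tested genes in each list at 4-6 h.

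At 0-2 h, leaving out wild-type 0-2 h replicate 1 left 62 calls in place of 289 and leaving out replicate 2 left 119. The shift to ribosomal protein genes moved the median of all genes by 0.26 at 0-2 h and -0.30 at 4-6 h. It gave 37 lower and 669 higher at 0-2 h and 2236 and 92 at 4-6 h. Median centring, which moved the median by 0.15, gave 1454 and 1141 at 4-6 h, and the deposited values gave 1189 and 41. The splits at 0-2 h were 34 and 29 after the shift to rpA1 and rp49, 167 and 117 with median centring and 45 and 100 in the value tables.

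**Figure D2:**
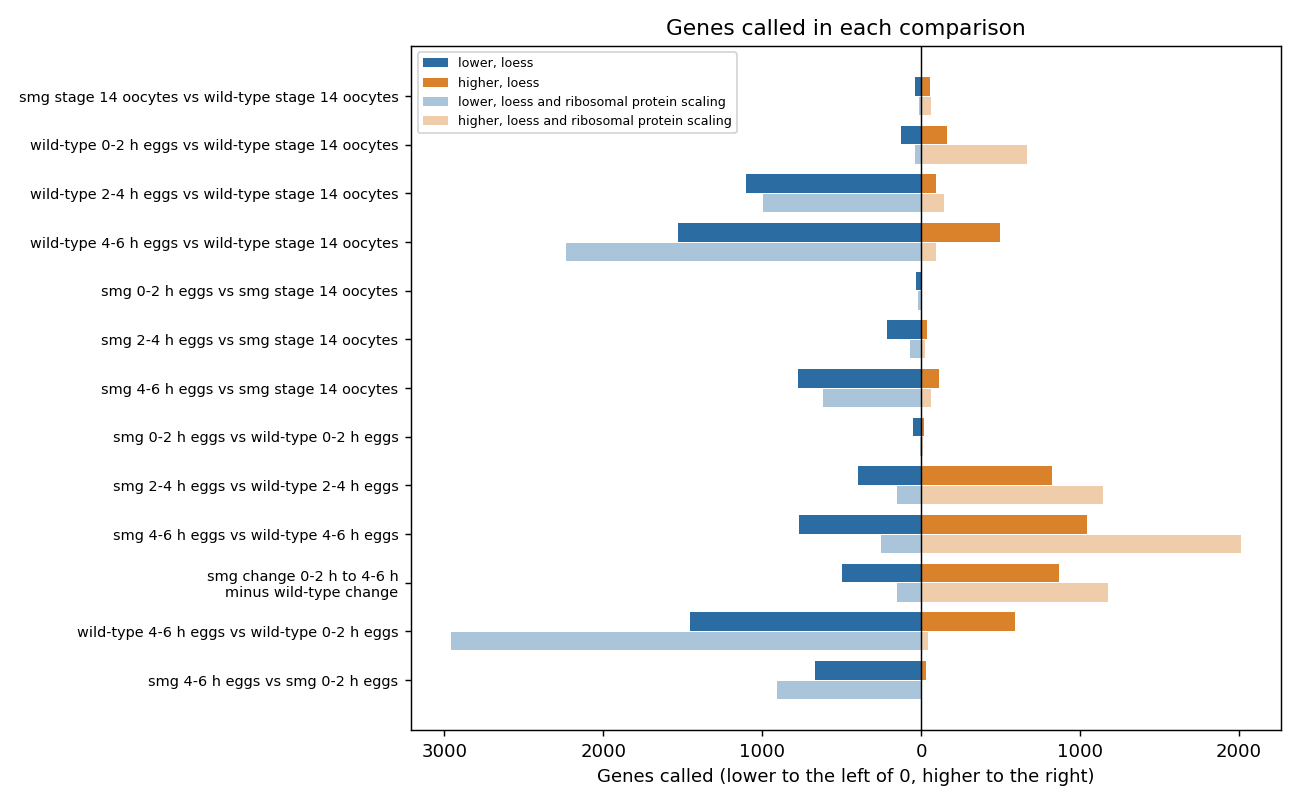
Number of transcripts called lower and higher (horizontal bars) in each comparison, with pale bars after the shift to ribosomal protein genes. The counts rose from 126 lower at 0-2 h to 1527 at 4-6 h in wild type and from 30 to 773 in smg. The number called higher depended on the processing of the arrays, with 495 in wild type at 4-6 h and 92 after the shift to ribosomal protein genes. It was 158 without background subtraction and 41 in the value tables, which lack both background subtraction and loess.

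The smg time course asked which maternal transcripts still fell in eggs of smg females. Hsp83 was 0.017 ± 0.29 at 4-6 h relative to smg stage 14 oocytes (adjusted p = 0.98), whereas stg fell by 2.11 ± 0.18 (adjusted p = 1e-07) and osk by 1.39 ± 0.26 (adjusted p = 0.0007). The largest falls by fitted change were in Yp1 (at least 26.5-fold), Yp2 (at least 9.79-fold), Yp3 (-3.81 ± 0.43), Jon99Fii (at least 9.03-fold), the oligopeptide transporter yin (at least 9.34-fold) and exu (at least 6.15-fold). Jon99Fii was not called without smg stage 14 replicate 1 or smg 4-6 h replicate 2. The largest gains were in borr, of the chromosomal passenger complex (1.42 ± 0.38), BomT3 (1.12 ± 0.24) and the endocytic protein gene Ehbp1 (1.08 ± 0.29). They were followed by NTPase, a nucleotidase (1.04 ± 0.24), and CIAPIN1, for cytosolic iron-sulfur clusters (1.03 ± 0.22, but 0.46 as the mean of its probes). Of these gains, borr and Ehbp1 lost their calls when 1 array was left out. This array was smg stage 14 replicate 1 for borr (1.31) and Ehbp1 (0.66). It was also smg 4-6 h replicate 2 for Ehbp1 (0.96) and replicate 3 for borr (1.09). Only CIAPIN1 of these 5 stayed called in the value tables. bcd fell by 0.71 ± 0.15 (adjusted p = 0.0015), a call lost after median centring, the shift to rpA1 and rp49, and in the value tables (-0.52, -0.71 and -0.65). RpL32, Hsp26 (-0.57 ± 0.33), CycB (0.42 ± 0.19) and smg (-0.53 ± 0.24) were not called, the last reaching the threshold without smg 4-6 h replicate 1 (-0.86).

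Calls in smg eggs relative to smg oocytes numbered 30 lower and 0 higher at 0-2 h, 212 and 37 at 2-4 h, and 773 and 114 at 4-6 h, with 444 and 9 of at least 2-fold at 4-6 h. For the 0 higher from limma at 0-2 h, 104 genes had an unadjusted p under 0.05. Calls in both directions numbered 27 with a trend and robust prior and 148 with array quality weights. The transcripts lower at 0-2 h included Yp1 (at least 34.3-fold lower), Yp3 (-4.50 ± 0.43) and flw, a catalytic subunit of protein phosphatase 1 (-2.98 ± 0.38). Of 6 yolk and fat body genes 3 fell at each age, and at 2-4 h 4 when adjusted over the list alone (adjusted p = 7.1e-07, and 0.0056 with an estimated correlation). At 4-6 h the list test gave adjusted p = 0.013, and 0.16 with an estimated correlation.

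Of 22 germ plasm and germline genes 7 fell and 1, krimp (0.66 ± 0.16), rose at 4-6 h, with exu, the germline gene otu (-2.19 ± 0.28) and swa, which acts in bcd localization (-2.11 ± 0.27), the farthest down. Of 41 cell cycle genes 7 fell and 1 rose, with stg, gnu (-1.75 ± 0.30) and gwl, the Greatwall kinase (-1.33 ± 0.18). Of 15 meiosis and egg activation genes 3 fell and 1 rose, with sra, a calcineurin regulator (-1.78 ± 0.17), gnu and cort, an activator of the anaphase-promoting complex (at least 1.55-fold). The median of this list was 0.11 where its mean was -0.17. Of 26 mRNA decay genes 4 fell and 0 rose, with gnu, orb (-1.31 ± 0.19) and brat (-0.95 ± 0.18), both RNA-binding translational regulators. The call of brat was lost after the shift to rpA1 and rp49. With camera none of these 4 list tests passed, with adjusted p = 0.86, 0.86, 0.86 and 0.90 with an estimated correlation. Of 24 DNA replication genes Mcm6, of the replicative helicase, rose by 0.69 ± 0.17 and tos, an exonuclease, fell by 0.76 ± 0.21, and the median was 0.31 (adjusted p = 0.013, and 0.16 with an estimated correlation).

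In the remaining lists the falls were those of RpLP0 (-1.43 ± 0.29, 1 of 74 ribosomal protein genes), Hex-A, hexokinase (-1.60 ± 0.32, 1 of 11 glycolysis genes), ND-PDSW, of complex I (-1.32 ± 0.26, 1 of 18 oxidative phosphorylation genes), and BigH1 (-1.13 ± 0.20, 1 of 4 histone genes). Smaller ones were those of the proteasome subunit Prosbeta4 (-0.89 ± 0.23, 1 of 34; -0.60 and not called as the mean of its probes) and the mitochondrial chaperones Hsc70-5 (-0.83 ± 0.26; -0.51 and not called as the mean of its probes) and Hsp60A (-0.71 ± 0.23), 2 of 13 chaperone genes and 0 after the shift to rpA1 and rp49. Of these, Prosbeta4 lost its call without smg 4-6 h replicate 2 (-0.62), Hsp60A without that array (-0.47) or any smg stage 14 array (-0.67 to -0.77), and Hsc70-5 without smg 4-6 h replicate 1 (-0.65) or smg stage 14 replicate 2 or 3 (-0.69 and -0.88). So did Mcm6 without smg stage 14 replicate 1 (0.60) and tos without smg stage 14 replicate 2 (-0.67) or smg 4-6 h replicate 3 (-0.68). With limma, 0 of 17 translation factors (eIF4A 0.090 ± 0.16), 0 of 3 small heat shock genes, 0 of 13 tubulins and actins (Act88F -0.10 ± 0.18), 0 of 7 muscle genes, 0 of 2 follicle cell genes (slbo -0.079 ± 0.19) and 0 of 11 early zygotic genes (odd -0.13 ± 0.16) were called. Counts adjusted over the list alone were the same in each list.

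Within slide series B (2 smg 4-6 h arrays and 3 smg stage 14 arrays) 672 transcripts were lower and 123 higher, against 408 and 5 after the shift to rpA1 and rp49 and 362 and 2 in the value tables for all arrays. At 0-2 h, leaving out 1 of smg 0-2 h replicate 1 or 2 or smg stage 14 replicate 1 or 3 left 15, 16, 16 or 17 of 30 calls. Within series B the counts were 21 and 0. At 2-4 h, calls fell from 249 to 102 without smg 2-4 h replicate 2, 143 without replicate 3, 148 without replicate 1, and 108, 116 and 116 without smg stage 14 replicates 1, 2 and 3. The splits at 2-4 h were 109 and 0 after the shift to rpA1 and rp49, 68 and 26 after the shift to ribosomal protein genes, 29 and 0 in the value tables, and 50 and 1 within series B. These shifts moved the median of all genes by 0.22 and 0.19 at 0-2 h and -0.13 and 0.12 at 2-4 h.

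The comparison of smg with wild-type eggs at 4-6 h asked directly which transcripts differed when wild-type decay was well advanced. Hsp83 was 3.74 ± 0.29 higher in smg eggs (adjusted p = 3.7e-09) and osk at least 4.99-fold higher. The largest differences by fitted change were those of vig2 (4.62 ± 0.27), del (at least 16.4-fold), Hsp27 (4.39 ± 0.27), drpr (4.24 ± 0.27), RnrS (4.18 ± 0.30) and srl, the fly PGC-1 (4.15 ± 0.19). Lower in smg eggs were MSBP, a membrane steroid-binding protein (-2.43 ± 0.23), Dok, an adaptor of tyrosine kinases (-2.42 ± 0.17), and the insulator protein gene Elba2 (at least 3.71-fold). Lower too were the initiator caspase Dronc (-2.30 ± 0.16), cue (-2.25 ± 0.22) and msl-3, of the dosage compensation complex (at least 2.68-fold). stg (-0.81 ± 0.18, adjusted p = 0.0015) and bcd (-0.79 ± 0.15, adjusted p = 0.00021) were lower. Both calls were lost after the shift to rpA1 and rp49 (-0.60 and -0.58), the shift to ribosomal protein genes (-0.37 and -0.35) and in the value tables (-0.61 and -0.60). CycB was 0.25 ± 0.19 and reached the threshold only after the shift to ribosomal protein genes (0.69).

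Calls numbered 770 lower and 1047 higher in smg eggs, with 330 and 685 of at least 2-fold. Of 24 DNA replication genes 15 were higher and 0 lower, with RPA1 at 3.83 ± 0.19 and Gnf1 at 3.14 ± 0.19. With the other scalings 12 to 17 were higher (2 lower after median centring), and the list test gave adjusted p = 1.4e-05, and 0.02 with an estimated correlation. Of 11 glycolysis genes 7 were higher, with PyK at least 6.39-fold, Gapdh1 3.00 ± 0.24 and Gapdh2 2.76 ± 0.37 (adjusted p = 0.00043, and 0.21 with an estimated correlation). Of 13 chaperone genes 9 were higher, with CCT7 at 3.44 ± 0.23 and DnaJ-1 at 2.42 ± 0.25, or 1.70 as the mean of its probes (adjusted p = 9.1e-05, and 0.18 with an estimated correlation). All 3 small heat shock genes were higher, Hsp26 by 3.36 ± 0.33 and Hsp23 by 1.11 ± 0.24 (adjusted p = 0.0011, and 0.10 with an estimated correlation). Of 22 germ plasm genes 11 were higher and 2 lower, 12 and 2 when adjusted over the list alone. They included krimp at 3.49 ± 0.16, bru1, a translational repressor, at 2.67 ± 0.29 and piwi, of the piRNA pathway, at 2.62 ± 0.17 (adjusted p = 0.0034, and 0.28 with an estimated correlation). Of 26 mRNA decay genes 10 were higher and 2 lower, 11 and 3 over the list alone. Among them were twin at 2.13 ± 0.20, Pop2 at 1.73 ± 0.17 and Fmr1, the fragile X protein, at 1.52 ± 0.27, which was 0.61 with slide series as a fixed block (adjusted p = 0.03, and 0.28 with an estimated correlation). Of 41 cell cycle genes 15 were higher, with endos at 3.46 ± 0.18, the PP2A subunit tws at 2.82 ± 0.17 and Cks30A at 2.26 ± 0.21, and 8 lower (adjusted p = 0.084). Of 15 meiosis genes 6 were higher, with mtrm at 2.65 ± 0.30 and nod at least 2.03-fold, and 2 lower, with sra at -2.13 ± 0.17. Of 34 proteasome genes 13 were higher, with Rpn1 at least 9.20-fold, Rpn7 3.21 ± 0.21 and Rpn3 2.73 ± 0.27, or 1.10 as the mean of its probes, and 6 lower, 15 and 7 over the list alone (adjusted p = 0.16).

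Of 74 ribosomal protein genes 28 were lower in smg than in wild-type eggs and 1 higher, RpL23 (at least 2.33-fold), with a median of -0.51 (adjusted p = 2.2e-06, and 0.32 with an estimated correlation). The counts were 6 and 1 after the shift to rpA1 and rp49, 7 and 4 after the shift to these genes (median -0.075) and 3 and 1 in the value tables. Among them were sta (-1.51 ± 0.36) and RpLP0 (-1.42 ± 0.29). RpL32 was -0.95 ± 0.21, a call lost in these scalings (-0.74, -0.51 and -0.52). Its other gene probe, under the reference level, had log2 ratios of 0.270 in smg and 1.12 in wild-type 4-6 h eggs. The mean of all 20 rp49 spots, control spots included, was 0.0870, -0.0390 and -0.0781 on the smg 4-6 h arrays. On the wild-type 4-6 h arrays it was -0.0837, 0.251 and -0.0825, so these spots showed no such difference. Of 18 oxidative phosphorylation genes 4 were lower, with ND-PDSW at -1.76 ± 0.26 and SdhB at -1.01 ± 0.21, and 3 higher, with ATPsynbeta at 3.06 ± 0.24. The median of -0.26 (-0.18 with undetected genes at the empty-spot level) became 0.17 after the shift to ribosomal protein genes. Of 4 histone genes 2 were lower, His3.3A (-0.93 ± 0.19; -0.47 and not called as the mean of its probes) and His3.3B (-0.63 ± 0.20; -0.41 without smg 4-6 h replicate 2 and -0.59 without wild-type 4-6 h replicate 3). With 3 of 4 other scalings 0 were lower, and the median of -0.32 became 0.11 after the shift to ribosomal protein genes. Of 17 translation factors eIF4E1 (1.63 ± 0.23) and eIF2alpha were higher, the latter at 0.60 ± 0.22 (adjusted p = 0.037; 0.46 without smg 4-6 h replicate 3 and 0.34 without wild-type 4-6 h replicate 1, both not called). Of 13 tubulins and actins alphaTub67C, the maternal alpha-tubulin, was 0.95 ± 0.31, but -0.039 with slide series as a fixed block and not called without wild-type 4-6 h replicate 2 (0.47) or smg 4-6 h replicate 1 (0.88). Of the markers of other cell types, 1 of 6 yolk and fat body genes was called, Lsp1gamma (0.60 ± 0.22), and 0 over the list alone. It was not called without any 1 of the smg 4-6 h arrays (0.58 to 0.61), wild-type 4-6 h replicate 1 (0.43) or smg 0-2 h replicate 2 (0.60). With limma, 0 of 7 muscle genes (Act88F -0.087 ± 0.18), 0 of 2 follicle cell genes (slbo 0.49 ± 0.19, at least 1.5-fold without smg 4-6 h replicate 1, 0.59) and 0 of 11 early zygotic genes (odd 0.016 ± 0.16) were called.

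Within slide series D, which held 1 array of each group, 496 transcripts were lower and 556 higher. The split of calls was 248 lower and 990 higher after the shift to rpA1 and rp49, 251 and 2013 after the shift to ribosomal protein genes, 1244 and 855 after median centring and 168 and 560 in the value tables. The first 3 moved the median of all genes by 0.21, 0.43 and -0.21.

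**Figure D3:**
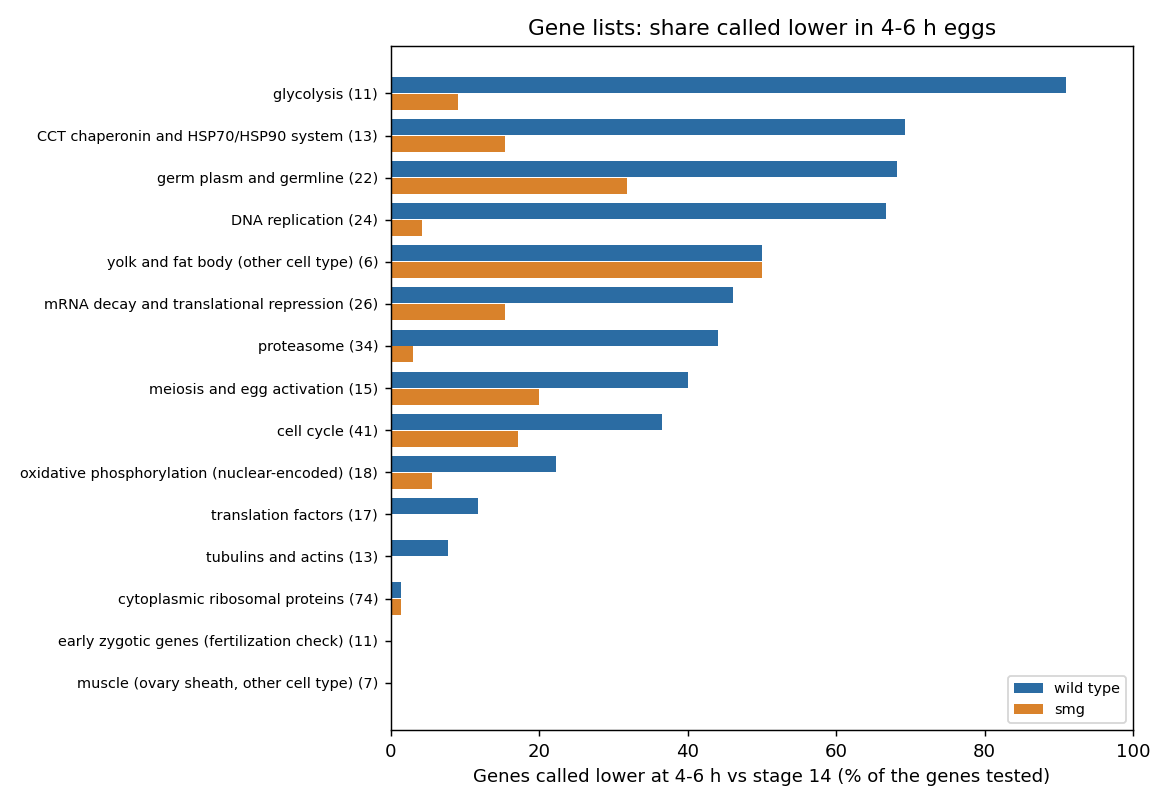
Percent of the tested genes of each list (vertical axis, lists with at least 5 tested genes) that were called lower at 4-6 h relative to stage 14 oocytes (horizontal axis), for wild type and smg. In glycolysis 10 of 11 genes were lower in wild type and 1 in smg, and in DNA replication 16 and 1 of 24. With other scalings these counts stayed at 10 and 1 for glycolysis and 14 to 17 and 0 or 1 for DNA replication.

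Earlier ages showed when the genotypes parted. At 2-4 h drpr (4.09 ± 0.27), the thioredoxin dhd (4.05 ± 0.30), vig2 (2.94 ± 0.27), RnrS (2.61 ± 0.30), osk (1.64 ± 0.26) and Hsp83 (1.40 ± 0.29) were higher in smg eggs. Lower were ND-PDSW (-2.03 ± 0.26), sra (-1.21 ± 0.17) and Dok (-0.72 ± 0.17). Calls numbered 395 lower and 825 higher. Of 24 DNA replication genes 15 were higher and 1 lower, 16 and 1 when adjusted over the list alone (adjusted p = 2.7e-05, and 0.02 with an estimated correlation). At 0-2 h Hsp83 differed by 0.0034 ± 0.29 and osk by -0.073 ± 0.26. The 50 transcripts lower in smg eggs at 0-2 h included the cadherin kug (-2.17 ± 0.41) and the phosphatase Ptp69D (-1.58 ± 0.27). The 20 higher included Arc1 (1.34 ± 0.23), cort (1.34 ± 0.29) and Usp14 (1.19 ± 0.22), of which Arc1 and Usp14 were also higher in stage 14 oocytes.

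At 2-4 h the split was 117 lower and 496 higher after the shift to rpA1 and rp49, 151 and 1145 after the shift to ribosomal protein genes, which moved the median by 0.19, and 9 and 491 in the value tables, which moved it by 0.11. Within slide series B (1 smg array and 2 wild-type arrays) it was 159 and 401. At 0-2 h no slide series held arrays of both genotypes, and limma with slide series as a fixed block called 0 transcripts, with 282 lower and 276 higher at an unadjusted p under 0.05. The 70 calls of limma without a block became 3 without smg 0-2 h replicate 1, 21 without replicate 2, 42 without replicate 3, 6 without wild-type 0-2 h replicate 1 and 34 without replicate 2, and 372 with array quality weights. The split was 2 lower and 23 higher after the shift to rpA1 and rp49, which moved the median by 0.34. It was 5 and 9 after the shift to ribosomal protein genes, 19 and 21 after median centring, which moved it by 0.11, and 5 and 4 in the value tables.

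The fate in smg eggs of the 1527 transcripts lower in wild-type 4-6 h eggs was then followed. Hsp83, drpr, vig2, Gapdh1, RPA1, endos and piwi belonged to the class, were higher in smg eggs and were not called lower than in smg oocytes. Yp1, exu and stg, also of the class, fell in both genotypes, and so did osk, which was still higher in smg than in wild-type eggs. In smg 4-6 h eggs 432 of the class (28.3%) were called lower than in smg oocytes, against 203 if the calls were independent (Fisher's exact test, two-sided, odds ratio 4.56, p = 1.6e-79). That p-value counts genes, which are not independent replicates, and does not measure the spread between arrays. With the class taken anew under each setting, the count of 432 became 235 without background subtraction and in the value tables and 281 after the shift to rpA1 and rp49. Higher in smg than in wild-type eggs were 4 of the class at 0-2 h, 629 (41.2%) at 2-4 h and 847 (55.5%) at 4-6 h, the last against 275 if independent. The count at 4-6 h was 525 without background subtraction, 524 in the value tables and 1465, of the 2236 transcripts then lower in wild type, after the shift to ribosomal protein genes. This pair of calls shares the wild-type 4-6 h arrays, and in 20 simulations of that sharing without a genotype difference the highest count was 0. Without such a difference hardly any genotype calls can arise. The simulations therefore cannot show how much the sharing adds to the 847. Of the class, 755 (49.4%) were higher in smg eggs and not lower than in smg oocytes, 340 (22.3%) were lower than in smg oocytes and not higher than in wild type. A further 92 (6.02%) were both and 340 neither, and 38 were lower in smg than in wild-type eggs.

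The median change of the class in smg eggs was -0.0011 at 0-2 h, -0.12 at 2-4 h and -0.31 at 4-6 h relative to smg oocytes, the last -0.24 with undetected transcripts at the empty-spot level. Across genes, which are not independent replicates, the 4-6 h changes of both genotypes correlated with r = 0.349. Of the 773 transcripts lower in smg 4-6 h eggs, 432 (55.9%) were in the class and 341 (44.1%) were not. Among those not lower in wild type were Dok (-1.98 ± 0.17 in smg, 0.62 ± 0.12 in wild type), MSBP (-2.20 ± 0.23 and 0.095 ± 0.16), Dronc (-1.54 ± 0.16 and 0.52 ± 0.11) and sra (-1.78 ± 0.17 and 0.017 ± 0.12). Taken from the 1101 transcripts lower at 2-4 h in wild type, the class had 591 (53.7%) higher in smg at 4-6 h, against 198 if independent. That pair of calls shared no sample arrays. Taken from the 1453 lower in wild-type 4-6 h than 0-2 h eggs, a comparison free of dye bias, 367 (25.3%) were lower in smg 4-6 h eggs than in smg oocytes and 319 (22%) than in smg 0-2 h eggs.

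**Figure D4:**
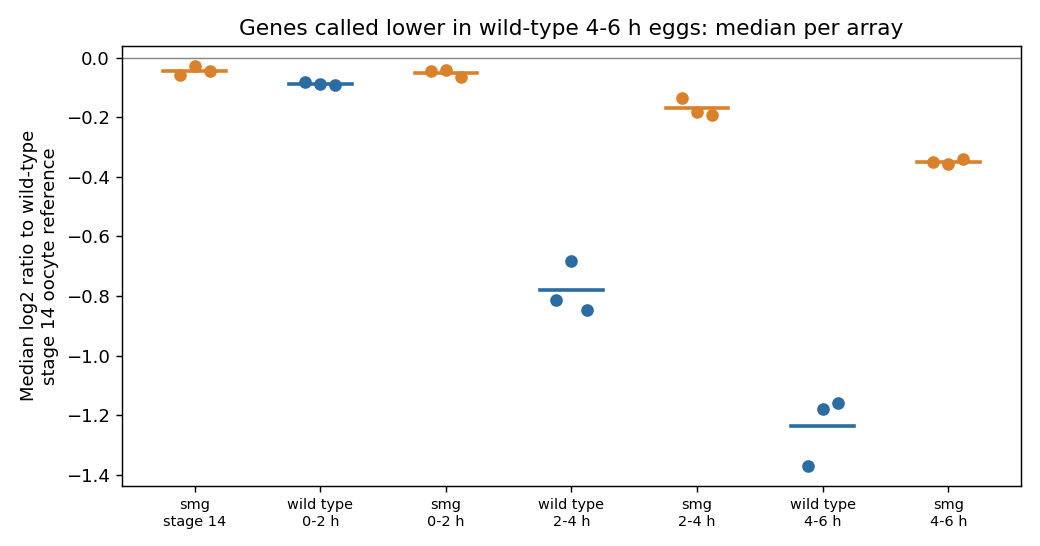
Median log2 ratio to wild-type stage 14 oocytes (vertical axis) of the 1527 transcripts lower in wild-type 4-6 h eggs, 1 point per array, by group (horizontal axis). The wild-type 4-6 h arrays, which also define the class, lay between -1.37 and -1.16 and the smg 4-6 h arrays between -0.36 and -0.34.

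Whether the change from 0-2 h to 4-6 h differed between genotypes was tested as an interaction. The change in smg eggs minus that in wild-type eggs was 4.60 ± 0.38 for Hsp27, 3.74 ± 0.41 for Hsp83 (adjusted p = 1.5e-06) and 3.70 ± 0.26 for RPA1, and -2.39 ± 0.24 for Dok and -2.35 ± 0.32 for MSBP. It was at least 24.8-fold higher for del and 5.24-fold for osk. For stg it was -0.49 ± 0.26 (adjusted p = 0.18). In all, 865 transcripts had a higher and 499 a lower change in smg, and 679 of the class of 1527 (44.5%) were among the higher. Of 24 DNA replication genes 11 were higher and 0 lower (adjusted p = 0.00047, and 0.073 with an estimated correlation), and of 22 germ plasm genes 11 and 2 (adjusted p = 0.002, and 0.25 with an estimated correlation). The split was 151 lower and 1179 higher after the shift to ribosomal protein genes, 967 and 561 after median centring and 42 and 373 in the value tables. The shifts to rpA1 and rp49 and to ribosomal protein genes and median centring moved the median by -0.13, 0.38 and -0.28.

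Within each genotype the eggs of 4-6 h and 0-2 h were compared without the oocyte reference. In wild type the change was -4.29 ± 0.27 for Hsp27 and -3.57 ± 0.29 for Hsp83, and del was at least 21.0-fold and osk at least 9.18-fold lower. Of 22 germ plasm genes 14 fell and 0 rose. Calls numbered 1453 lower and 592 higher, the latter with EMC1 (1.80 ± 0.44). Among them were 38 of 74 ribosomal protein genes against 1 lower, 41 and 1 when adjusted over the list alone (adjusted p = 3.7e-12, and 0.12 with an estimated correlation). In smg exu was at least 6.84-fold lower, and the change was -2.08 ± 0.18 for stg, -2.27 ± 0.23 for MSBP, -0.81 ± 0.26 for osk and 0.17 ± 0.29 for Hsp83 (adjusted p = 0.78). Calls in smg numbered 670 lower and 28 higher. Within slide series D the wild-type counts were 1050 and 573 (1 array against 3). The smg counts were 451 and 22 within series B (2 against 2) and 125 and 3 within the scan day that held 1 array of each. The wild-type split was 1154 and 151 after the shift to rpA1 and rp49, 2960 and 46 after the shift to ribosomal protein genes (median moved by -0.57), 1095 and 1155 after median centring (0.22) and 1228 and 48 in the value tables (-0.14). In smg the first pair of shifts moved the median by -0.22 and -0.18.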

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

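The tests of other groupings of the arrays and the tests weighed for the 3 patterns in this part were chosen after the results were seen, while the interaction between genotype and age was planned.

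The change from 0-2 h to 4-6 h differed between smg and wild-type eggs for 1364 transcripts in the interaction test, which brought this result here. Of 100 free regroupings of the 12 egg arrays, the real one included, 2 gave as many calls, with 1493 for the highest other, but such regroupings also break the effects of age and genotype and do not test the interaction alone. When only the residuals of an additive fit of age and genotype were moved between the arrays, 1 of 100, the real one, gave as many calls, with 564 for the highest other. Chance spread between arrays is argued against at that share. Chance between collections of eggs was not tested, as the arrays may be repeated hybridizations, and the groups also differed in slide series. The comparisons of 3 with 3 arrays allow 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls in each. The real value and the highest other were 30 and 0 for smg 0-2 h eggs against smg stage 14 oocytes, 249 and 1 at 2-4 h, 887 and 0 at 4-6 h, 70 and 0 for smg against wild-type eggs at 0-2 h, 1220 and 1 at 2-4 h, 1817 and 1 at 4-6 h, 2045 and 2 for wild-type 4-6 h against 0-2 h eggs, and 698 and 0 for the same ages in smg.

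Of the 968 buffer spots, which are outside the comparisons, a median of 62.6% over arrays (17.0% to 83.2%) lay above the 95th percentile of empty spots in the reference channel, against 9.95% (4.65% to 28.3%) of failed spots and an expected 5%. The same percentile in Cy3 set the level of detection and the values given as at least a number of folds. A spot above it may thus lack signal of its transcript, and those values are not firm bounds. The share of buffer spots above it in Cy3 is not given here. Of 4505 genes under the reference level of 3000, which the comparisons left out, 35 were called higher and 8 lower in wild-type 4-6 h eggs against stage 14 oocytes. At 0-2 h against stage 14 oocytes the counts were 1 and 1. From wild-type 0-2 h to 4-6 h eggs, where dye bias cancels, 0 were called higher and 0 lower. The 35 were thus seen only against the reference, and their cause was not tested.

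The first pattern was a set of 16 transcripts lower by 0-2 h in both genotypes, of 126 lower in wild type and 30 in smg, where 0.65 would be shared by independent lists. They included Yp1, Yp2, Yp3, flw, Gp150, CHKov1 and Asph, with a median of -1.51 in wild type (-1.32 with undetected genes at the empty-spot level), -3.12 in smg (-2.81) and 1.18 in smg stage 14 oocytes against the reference. Carry-over of ovary muscle with the oocytes stays open, because the 7 muscle genes (median -0.0202, SD 0.25, at 0-2 h in wild type, 0 called) were near the reference level or had a high signal of their own, and only 1 lay between. Follicle cells, which make yolk proteins, may be the source and stay open, since only 2 of their markers were tested (median 0.0411, slbo among them). Decay after egg activation stays open as well, since the set changed by a median of only -0.326 (SD 0.75) from 0-2 h to 4-6 h in wild type. With undetected genes at the empty-spot level this median was -0.223. Of the 16, 11 were not above empty spots at 0-2 h or 4-6 h, 5 of them at both ages, so a further fall could hardly be seen. The small change neither needs nor forbids an early loss.

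The second pattern was a run of lower transcripts beside smg on chromosome arm 3L in smg stage 14 oocytes. Of the 10 tested genes on one side, 5 were lower (Tsp66E, Srp68, CG5068, pix and CG5026) and 0 of 10 on the other side (Fisher's exact test for the 20 against other genes, two-sided, odds ratio 53.7, p = 1.9e-07), with medians of -0.511 and -0.0628. The p-value counts genes, which are not independent replicates. It rests on calls with loess alone, as does the count of windows below. Of all tested genes only 4 were lower after the shift to rpA1 and rp49 and 3 in the value tables. Not all 5 neighbours can thus have been called there. After the shift to ribosomal protein genes 14 of all tested genes were lower, and 40 after median centring. A faulty area of the slide was argued against, as the 5 genes lay in 5 print grids, and so was dye bias, as the 5 had a median of -0.667 (SD 0.34) between smg and wild-type eggs at 0-2 h, where it cancels, with all 5 negative and 2 called, although at 4-6 h Srp68 (0.557) and Tsp66E (0.387) were positive. A candidate explanation is that the smg females carried fewer copies of this segment, as with a deletion over smg, since 0 of 5072 windows of 20 neighbours elsewhere held as many lower genes and the highest held 3, although the median of 1 such window was as low (-0.287, against -0.277 for the 20 beside smg). It stays open, because 2 of the 7 bright genes of that side, orb2 (0.025) and GNBP3 (-0.096), were not lower, the median of that side was -0.409 at 0-2 h, -0.520 at 2-4 h and -0.204 at 4-6 h between genotypes, and the labels name no allele.

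The third pattern was a set of 243 transcripts that were lower in smg 4-6 h eggs than in both smg stage 14 oocytes and wild-type 4-6 h eggs and not lower in wild type, among them MSBP, Dok, Elba2, Dronc, cue, msl-3, wdn, sra and BEAF-32, with a median of -1.0 in smg (-0.862 with undetected genes at the empty-spot level) and 0.0233 in wild type. Scaling of the arrays may be a cause of part of it and stays open, since 41 of them met the same criteria under each of 4 other scalings and the other 202 missed at least 1. The criteria were met by 208 with median centring, 100 and 76 after the shifts to ribosomal protein genes and to rpA1 and rp49, and 56 in the value tables. After the shift to ribosomal protein genes the medians were -0.991 in smg, -0.650 between genotypes at 4-6 h and -0.276 in wild type. That shift moved the median of all genes by 0.011, 0.43 and -0.30 in these comparisons. The shifted medians follow from the values that picked the set and from the shift, so they do not test scaling. The smg stage 14 arrays as the cause were argued against, since 202 of the 243 were also lower in smg 4-6 h than 0-2 h eggs (median -0.908). In smg stage 14 oocytes the set had a median of -0.0685 against the reference. The comparison with 0-2 h eggs reuses the smg 4-6 h arrays that picked the set, so it does not test those arrays. Slide series as a cause stays open. With slide series as a fixed block 162 were called lower in both comparisons. Series A held wild-type 4-6 h arrays only, so the block left 1 wild-type 4-6 h array, in series D, for the comparison between genotypes. That the smg genotype may speed the decay of such transcripts stays open as a hypothesis, as the labels word RNA extraction and labelling differently for the genotypes.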

How the results depend on the processing

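Alternatives with scan day and within 1 slide series or scan day were chosen after the data were seen, and the others were planned. Of 577 alternative values of 15 counts, 497 stayed within 1.5 times the reported count and 80 did not. Of 7317 alternative values of 193 values of named genes, 7052 kept direction and side of the threshold, 255 lost the call, 9 gained it and 1 reversed, alphaTub67C between smg and wild-type 4-6 h eggs, which was -0.039 with slide series as a fixed block; the cause was not tested. Of 24 list calls in the 4 main comparisons, from 76 list tests, 21 were lost with an estimated correlation. With fry 2 were lost and 15 gained. Total calls are given here in the order of each sentence. Except where fewer genes or arrays or the absence of a minimum fold shows it, the cause was not tested.

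Without background subtraction, calls were 44 for smg stage 14 oocytes, 140, 579 and 1077 for wild-type 0-2 h, 2-4 h and 4-6 h eggs against stage 14, 98 and 494 for smg 2-4 h and 4-6 h eggs against smg stage 14, 559 and 1161 for smg against wild type at 2-4 h and 4-6 h, 1275 and 411 for 4-6 h against 0-2 h in wild type and smg, and, of the transcripts lower in wild type under the same setting, 235 lower in smg and 525 higher in smg than in wild type. In the value tables, the same counts were 25, 145, 791, 1230, 29, 364, 500, 728, 1276, 302, 235 and 524, with 9 for smg against wild type at 0-2 h and 415 for the interaction. With the shift to rpA1 and rp49, calls were 53 for smg stage 14, 63 for wild-type 0-2 h, 18, 109 and 413 for smg 0-2 h, 2-4 h and 4-6 h against smg stage 14, 25 and 613 for smg against wild type at 0-2 h and 2-4 h, 547 for the interaction, 1305 for wild-type 4-6 h against 0-2 h, and 281 of the transcripts then lower in wild type that were lower in smg. With the shift to ribosomal protein genes, they were 706 for wild-type 0-2 h, 19 and 94 for smg 0-2 h and 2-4 h against smg stage 14, 14 for smg against wild type at 0-2 h, and 1465 higher in smg of the 2236 transcripts then lower in wild type. Median centring gave 40 for smg against wild type at 0-2 h.

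With no reference filter that comparison gave 34. With a reference of at least 5000 (fewer genes), wild-type 0-2 h, 2-4 h and 4-6 h gave 181, 738 and 1281, smg 0-2 h against smg stage 14 gave 19 and smg against wild type at 2-4 h gave 812. Without a minimum fold, wild-type 0-2 h and 2-4 h gave 459 and 1854. Array quality weights gave 214 for smg stage 14, 148 and 571 for smg 0-2 h and 2-4 h against smg stage 14, and 372 for smg against wild type at 0-2 h. Slide series as a fixed block gave 97 for smg 2-4 h against smg stage 14 and 0 for smg against wild type at 0-2 h, where limma found 282 lower and 276 higher at an unadjusted p under 0.05. Within series B (fewer arrays), smg 2-4 h gave 51 against smg stage 14 and 560 against wild type, within series D smg against wild type at 4-6 h gave 1052, and smg 4-6 h against 0-2 h gave 128 within 1 scan day and 106 with scan day as a fixed block.

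With 1 array left out in turn, calls ranged from 35 to 110 for smg stage 14, 62 to 316 for wild-type 0-2 h, 15 to 35 and 102 to 308 for smg 0-2 h and 2-4 h against smg stage 14, and 3 to 89 for smg against wild type at 0-2 h. The other counts stayed within 1.5 times, such as 1869 to 2307 for wild-type 4-6 h, 652 to 939 for smg 4-6 h against smg stage 14 and 1609 to 1907 for smg against wild type at 4-6 h. Signal over background limits falls of weak transcripts, since 354 and 210 of the transcripts lower at 4-6 h in wild type and smg were not above empty spots, of which 163 and 128 fell at least 1.5-fold down to that level.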

Other observations

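The gene groups in this part were chosen after the data were seen, by shared symbols, and their tests are not independent of that choice. Groups of spliceosomal Sm and snRNP proteins, complex I, E2 ubiquitin-conjugating enzymes and ER chaperones were tested too. In smg stage 14 oocytes the 6 E2 genes had a median of -0.30, or -0.18 after the shift to ribosomal protein genes. Of them 0 were called (list test adjusted p = 0.0014, and 0.013 with an estimated correlation). The others gave adjusted p = 0.0055, 0.42 and 0.016 there, and 0.13, 0.51 and 0.17 with an estimated correlation. Of 17 genes of the vacuolar ATPase, the proton pump of endosomes and yolk-storing organelles, 11 fell in smg 4-6 h eggs relative to smg oocytes and 0 rose, 12 when adjusted over the list alone, with Vha68-1 at -1.61 ± 0.24, Vha44 at -1.54 ± 0.26 and Vha55 at -1.45 ± 0.18 (list test adjusted p = 8.5e-06, and 0.11 with an estimated correlation). In wild type 7 of the 17 fell and 0 rose, with Vha44 at -2.12 ± 0.18, and between genotypes at 4-6 h 3 were lower in smg and 0 higher (adjusted p = 0.056), against 0 and 2 after the shift to ribosomal protein genes. Of 31 mitochondrial ribosomal protein genes 1 was lower in smg stage 14 oocytes, 2 over the list alone, with a median of -0.22 (adjusted p = 0.0014, and 0.013 with an estimated correlation), but 0 with a median of -0.098 after the shift to ribosomal protein genes. In wild-type 4-6 h eggs 6 fell and 1 rose (adjusted p = 0.87). In smg eggs 7 fell, 8 over the list alone (adjusted p = 0.046, and 0.11 with an estimated correlation), and 11 were lower in smg than in wild-type eggs, 12 over the list alone (adjusted p = 0.0073, and 0.025 with an estimated correlation), but 4 lower and 3 higher after the shift to ribosomal protein genes, where the median changed from -0.35 (-0.20 with undetected genes at the empty-spot level) to 0.084. Among them mRpL18 was -1.98 ± 0.32 and mRpS5 -1.22 ± 0.21 in smg eggs.

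Of 14 genes of Sec proteins, which act in secretion, 9 fell in wild-type eggs and 3 in smg, and 6 were higher and 1 lower in smg than in wild type at 4-6 h, such as Sec61alpha (1.40 ± 0.25). Of 23 aminoacyl-tRNA synthetase genes 10 fell and 3 rose in wild type, 1 fell in smg, and 8 were higher and 1 lower in smg than in wild type. Of 11 condensin, cohesin and SMC genes 5 fell in wild type, such as SMC3 (-2.43 ± 0.20) and SMC1 (at least 2.27-fold), and 1 rose, glu (0.914 ± 0.18), with adjusted p = 0.37. In smg 1 fell, 0 over the list alone, with a median of 0.39 (adjusted p = 0.025, and 0.13 with an estimated correlation), and 6 were higher and 0 lower in smg than in wild-type eggs (adjusted p = 0.048, and 0.23 with an estimated correlation), with SMC3 at 2.91 ± 0.29 and SMC1 at least 3.64-fold. In the same comparisons, wild type over time, smg over time and smg against wild type, the counts lower and higher were 8 and 1, 5 and 0, and 4 and 4 for 15 Rab GTPases, 3 and 0, 2 and 1, and 1 and 4 for 8 kinesins, and 4 and 3, 0 and 1, and 4 and 3 for 14 nuclear pore genes. After the shift to ribosomal protein genes the counts between genotypes were 0 and 8 for Sec proteins, 0 and 12 for synthetases, 0 and 7 for condensin, cohesin and SMC genes, 2 and 5 for Rab GTPases, 0 and 4 for kinesins and 0 and 5 for nuclear pore genes, which in wild type were 4 and 0. With camera none of the list tests of the Sec proteins, synthetases, Rab GTPases, kinesins and nuclear pore genes between smg and wild type passed. Their adjusted p was 0.34, 0.34, 0.37, 0.34 and 0.96 with an estimated correlation. With fry it was 6.8e-05, 0.00075, 0.009, 4.6e-05 and 0.14, so only the nuclear pore genes failed both tests.

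Of 9 digestive enzyme genes, most of them close to the reference level of 3000, 5 were lower in wild-type 0-2 h eggs than in stage 14 oocytes (median -1.51, and -1.09 with undetected genes at the empty-spot level, adjusted p = 2.6e-05, and 0.093 with an estimated correlation) and in limma 0 in smg 0-2 h eggs against smg oocytes, with a median of -0.652. From 0-2 h to 4-6 h in wild type 3 were higher, Amy-d (1.65 ± 0.53), Amy-p (1.53 ± 0.38) and Jon65Ai, which was not above empty spots at either age, and 1 after the shift to ribosomal protein genes, with 1 lower. Their median in smg stage 14 oocytes against the reference was 0.574, and 0 were called, 4 higher when adjusted over the list alone. The list test there gave adjusted p = 0.0028, and 0.17 with an estimated correlation.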
